A study of Caenorhabditis elegans with 4 samples.

How the data were processed

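Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on *Caenorhabditis elegans* larvae of the wild-type N2 strain at the L3 stage, in a mixed population of males and hermaphrodites kept at 20 °C. The series holds 4 samples. They are 2 libraries of DNA precipitated with SDQ2340, an affinity-purified rabbit polyclonal antibody raised against HPL-2, and 2 input libraries of DNA that was not precipitated. Per the labels' protocols, ground frozen worms were crosslinked with EGS for 20 min and with EGS plus formaldehyde for a further 10 min, the chromatin was sonicated, and adaptor-ligated fragments were amplified by PCR and selected by size on a gel. Samples were grouped as HPL-2 ChIP or input by their titles, which also gave the replicate numbers.

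The deposited values analysed here are 3 peak lists, 1 for each ChIP replicate and 1 for the series as a whole. The input libraries were not analysed here. BWA and the genome build ce10 are named in the submitters' processing notes, without a version or parameters. Per the file headers, the coordinates are on WormBase WS220, and the source column of each list names MACS as the peak caller. The version, threshold and control library of MACS, and the way in which the replicates were combined into the series-level list, are not given in the sources used here. Each peak carries a score in the deposited lists, used here as given. The scale of the score (fold enrichment, or a log-transformed p or q value) is not stated, so the score was used only to rank or filter peaks within a list. Read depth is unknown from peak lists, and no interval given here includes sequencing error. The threshold of each list is unknown, so the absence of a peak from a list does not show absence of binding.

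Start and end positions were used as deposited, counted from 1. The length of each chromosome was taken as the largest end position over the 3 lists. Each chromosome was divided into 3 equal parts by length. The outer 2 parts are called arms and the inner part the centre, and a peak was assigned by its midpoint. Arm enrichment is the log2 ratio of peak density in the arms to that in the centre, tested over the 6 chromosomes with an exact sign-flip permutation test (two-sided, 64 sign assignments, smallest possible p = 0.03125). This test treats chromosomes of the same worms as its units, so it measures how regular a pattern is over chromosomes and not over animals. Peaks of different lists were called shared when they overlapped by at least 1 bp. The share was compared with 1000 random rotations of the other list along each chromosome, which keep the spacing of peaks. Clustering was the share of peaks with a neighbour at a gap of up to 1 kb, compared with 1000 random placements of the same peaks on the same chromosome without overlap. The smallest two-sided p that either comparison can give is 0.002. Intervals on shares of peaks are Wilson 95% confidence intervals and cover counting error only. Neighbouring peaks are not independent, so these intervals are too narrow.

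The series-level list was the main set for location, and each replicate list was analysed in the same way beside it. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical. The regions named were fixed by rule before the data were examined. They are the 10 highest-scoring series-level peaks found in both replicate lists (ties by width), the 5 widest regions after merging peaks over gaps of up to 1 kb, and the 100 kb window with most peaks on each chromosome. Regions chosen after their values were seen are named as such. The test of the difference in arm ratio between the replicate lists was also added after the data were examined. Gene annotation, the 27 gene lists fixed beforehand and sequence composition were not used here, because the gene table at hand is on WBcel235 and the peaks are on WS220. These 3 planned results are therefore not reported. Alternatives covered the overlap rule, the score threshold, the null placement, the definition of arms, base pairs in place of peak number, merged peaks, and each replicate list alone.

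The code was tested on simulated lists. In simulated lists of 20533 peaks, the number in replicate 1, a simulated arm ratio of 1 (log2) was recovered as 1.00 and a ratio of 0 as 0.0046. Independent lists, placed uniformly without an arm pattern or grouping, shared 12.5% of peaks against 12.8% after rotation (permutation test by 1000 random rotations, p = 0.094). This check does not cover independent lists that have an arm pattern in common. When 50% of the peaks were copied, 56.1% were found, chance overlap included. Uniformly placed peaks had a neighbour in 38.3% of cases against 38.6% at random (permutation test by 1000 placements, p = 0.38). Peaks simulated with the arm ratio of 1 had one in 40.4% (p = 0.002 in the same permutation test), so clustering was also compared with placement within the 3 parts of each chromosome. The checks on independent lists and on uniform placement were single draws. The computation was set to stop unless both gave p above 0.05, so they say nothing of the false-positive rate. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the overlap counts of the simulated lists were checked against bedtools 2.31.1, with equal results.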

Results

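The series mapped the occupancy of HPL-2 along the genome of wild-type L3 larvae, with 2 ChIP libraries and 2 input libraries. HPL-2 is a *C. elegans* member of the heterochromatin protein 1 family, whose chromodomain binds methylated histone H3. In the ChIP libraries, HPL-2 peaks numbered 20533 in replicate 1 and 16490 in replicate 2 (mean 18512 ± 2859, SD, n = 2). The series-level list held 23530 peaks. Peaks covered 8.50 Mb of the genome in replicate 1, 5.44 Mb in replicate 2 and 9.85 Mb in the series-level list, which is 8.48%, 5.43% and 9.82% of the 100.3 Mb spanned by the 6 chromosomes. Most peaks were narrow: the median width was 258 bp in replicate 1, 231 bp in replicate 2 and 259 bp in the series-level list, and the narrowest peak was 146 bp wide in every list. Broad peaks were few, with 52 series-level peaks wider than 5 kb, 38 in replicate 1 and 6 in replicate 2. Read depth is unknown from these lists.

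HPL-2 peaks were concentrated on the chromosome arms. To ask how binding is distributed along chromosomes, the density of peaks in the arms (the outer 2 of 3 equal parts of each chromosome) was compared with that in the centre. In the series-level list, all 6 chromosomes had more peaks per Mb on the arms than in the centre, by 2.25-fold on average (log2 ratio 1.17 ± 0.22, SD over 6 chromosomes, exact sign-flip permutation test, p = 0.03125, the smallest that 6 chromosomes can give). Chromosome IV had the largest ratio, with 290.6 peaks per Mb on the arms and 110.4 in the centre (2.63-fold). Chromosome I had 394.6 and 160.2 peaks per Mb (2.46-fold), chromosome III 411.5 and 171.1 (2.41-fold), chromosome II 283.4 and 123.3 (2.30-fold), and chromosome V 253.9 and 118.0 (2.15-fold). The X chromosome had the smallest ratio, with 149.2 peaks per Mb on the arms and 87.5 in the centre (1.71-fold). The mean profile over the 6 chromosomes, in twelfths of their length, was highest in the second twelfth, at 417 ± 185 peaks per Mb (SD over chromosomes), and lowest in the fifth twelfth, at 118 ± 34 peaks per Mb. The outermost left twelfth held 342 ± 150 and the outermost right twelfth 316 ± 101 peaks per Mb.

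**Figure D1:**
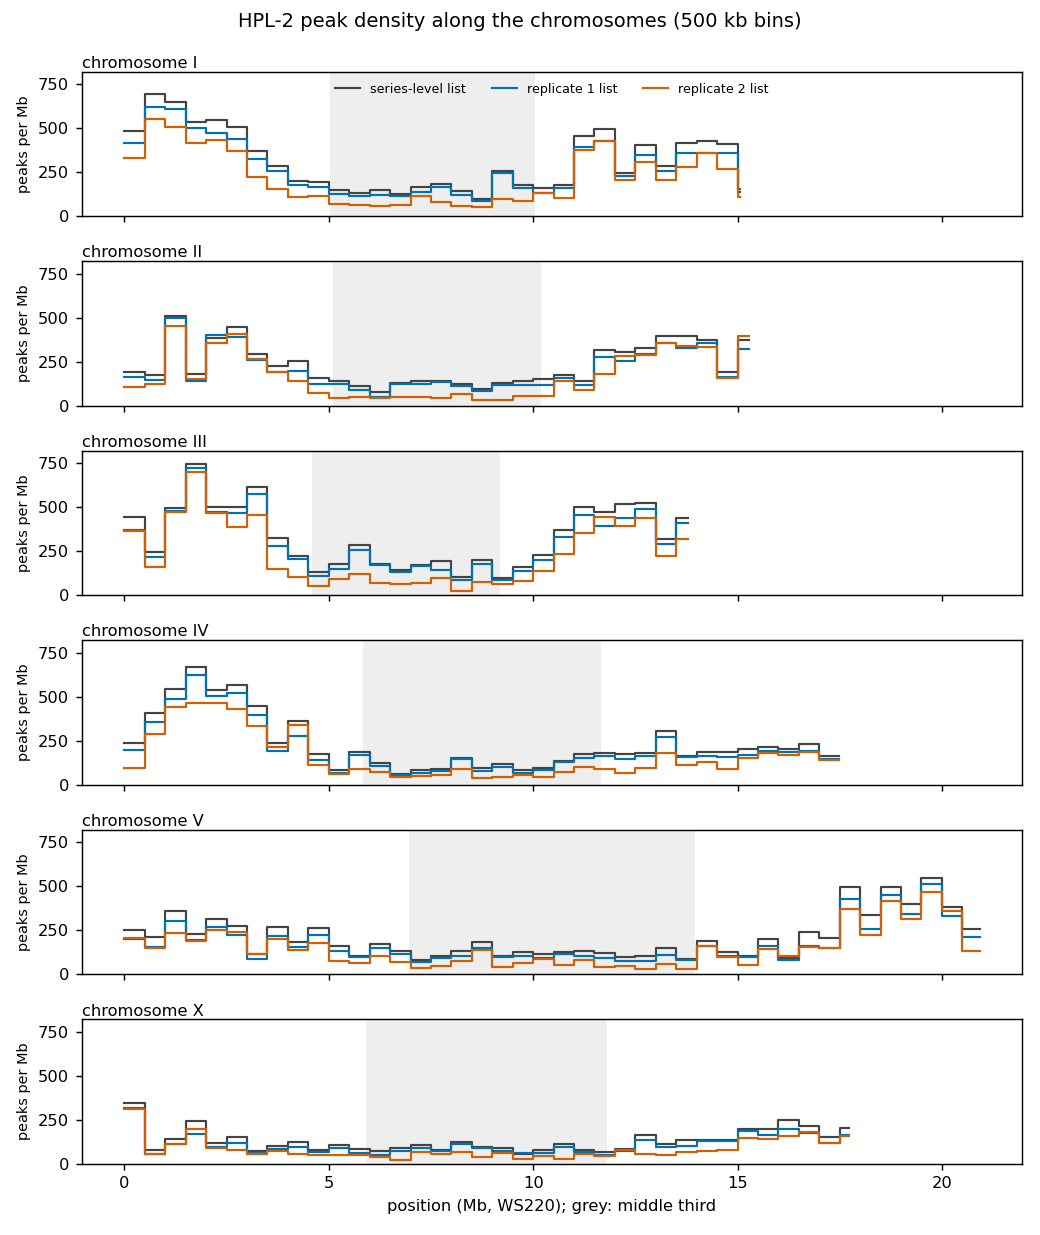
Peak density (peaks per Mb, 500 kb bins) against position (Mb, WS220) on each of the 6 chromosomes, for the series-level list (grey line), replicate 1 (blue) and replicate 2 (orange). The shaded stretch is the inner of 3 equal parts, and on every chromosome the density averaged over the arms lies above that of the centre in each list.

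Both replicate lists showed the arm pattern on all 6 chromosomes, and its size differed between them. The mean log2 ratio was 1.19 ± 0.23 (SD over 6 chromosomes) in replicate 1 and 1.83 ± 0.39 in replicate 2, or 2.28-fold and 3.55-fold. The ratio was higher in replicate 2 on 6 of 6 chromosomes, by 0.64 ± 0.25 on the log2 scale (exact sign-flip permutation test, p = 0.03125). This test of the difference was added after the data were seen. Chromosome II differed most, with a 2.35-fold ratio in replicate 1 and a 4.82-fold ratio in replicate 2. The 10234 series-level peaks found in both replicate lists had a mean log2 ratio of 1.92 ± 0.31, or 3.78-fold. Sorting by overlap itself favours the arms, where both replicate lists are denser. The size of the arm ratio therefore depended on the list by over 1.5 times, while its direction did not.

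The left and right arms of a chromosome were not equally occupied. On chromosome IV the left arm held 380.5 peaks per Mb and the right arm 200.6, a log2 ratio of right to left of -0.92 in the series-level list, -0.93 in replicate 1 and -1.11 in replicate 2. Chromosomes I and III also had the denser arm on the left, with ratios of -0.37 and -0.28. Chromosome V had the denser arm on the right, at 290.0 against 217.8 peaks per Mb (0.41). The X chromosome had a ratio of 0.22 in the series-level list, 0.27 in replicate 1 and 0.07 in replicate 2, so its size depended on the list. Chromosome II was nearly even (0.04, and 0.02 and 0.09 in the replicates). The sign of the ratio was the same in both replicate lists on all 6 chromosomes. No test was made of the difference between arms of 1 chromosome.

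**Figure D2:**
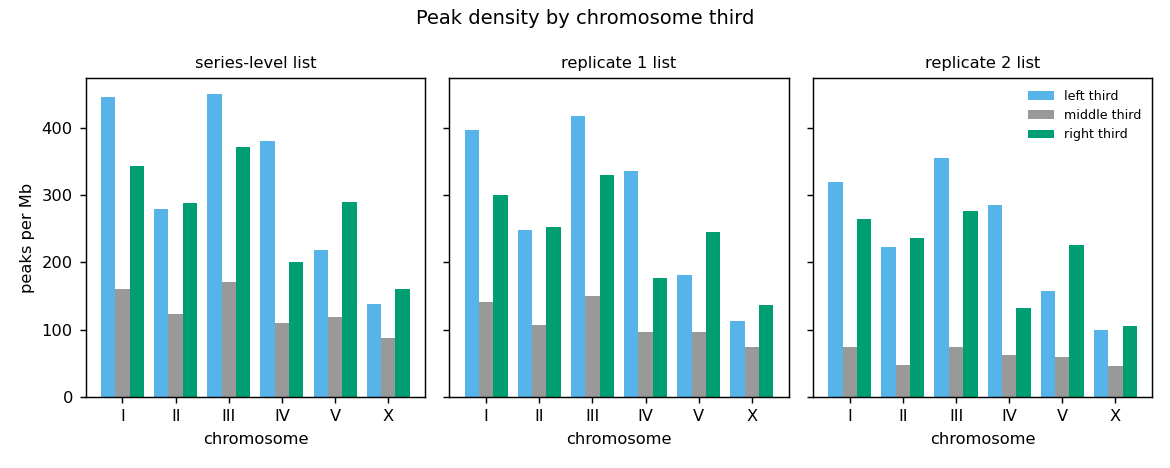
Bars give peaks per Mb in the left arm, centre and right arm (3 equal parts) of each chromosome, for each of the 3 lists. The centre is the lowest of the 3 bars on every chromosome in every list, and chromosome IV has its tallest bar on the left (380.5 peaks per Mb in the series-level list) and chromosome V on the right (290.0).

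The X chromosome was the least occupied chromosome. It carried 128.7 peaks per Mb in the series-level list, against 263.4 ± 56.2 (SD) over the 5 autosomes, whose lowest value was 208.6. The density of X was 0.489 of the autosome mean (log2 ratio -1.03). Replicate 1 gave 107.5 peaks per Mb on X against 231.7 ± 54.2 on autosomes, and replicate 2 gave 83.5 against 186.1 ± 38.6 (log2 ratios -1.11 and -1.16, mean -1.13 ± 0.035, SD, n = 2). The gap was present in both parts of the chromosome. In the series-level list X had 0.457 of the mean autosomal density on the arms and 0.641 in the centre. An exact one-sided permutation test of 1 chromosome against 5 cannot give a p below 0.167, so values alone are given, and the dose of X in this mixed population of males and hermaphrodites was not accounted for.

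HPL-2 peaks occurred in groups. In the series-level list 17189 of 23530 peaks (73.1%) had a neighbour at a gap of up to 1 kb, against 42.9% (range 41.8 to 44.1%) when the same peaks were placed at random on the same chromosome (permutation test by 1000 placements, two-sided, p = 0.002, the smallest they can give). With random placement kept within each of the 3 parts of the chromosome, so that each part kept its number of peaks, the expectation was 47.0% (same permutation test, p = 0.002). Density changes within a part were not kept, such as from 417 peaks per Mb in the second twelfth to 183 in the fourth. A broad domain called as several peaks would also count as a group. The observed share was 71.6% in replicate 1 and 64.9% in replicate 2, with 38.6% and 31.4% at random on the same chromosome. Merging peaks over gaps of up to 1 kb gave 10773 regions, of which 6341 held a single peak. Another 1119 regions held 5 or more peaks and together contained 37.1% of all peaks. Counted as merged regions, the arm ratio was smaller, at 0.80 ± 0.09 (log2, SD over 6 chromosomes) or 1.74-fold, and still above 0 on 6 of 6 chromosomes.

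The 5 widest merged regions all lay on autosome arms, 3 of them on chromosome II. The widest ran from 1320512 to 1355348 on chromosome II (34.8 kb, WS220) and held 43 series-level peaks that filled 66.9% of its length, with 47 peaks in replicate 1 and 46 in replicate 2. The next ran from 15189985 to 15220691 on the right arm of chromosome II (30.7 kb, 21 peaks, 88.7% of its length in peaks). A region of chromosome IV from 2880611 to 2908940 (28.3 kb) held 35 peaks. A region of chromosome III from 1162987 to 1189498 (26.5 kb) held 22 peaks, and a further region of chromosome II from 2451104 to 2477563 (26.5 kb) held 28. In every one of these 5 regions both replicate lists had at least 19 peaks.

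The 100 kb window with most peaks lay on an arm of each chromosome. On chromosome I it was the window from 2000001 to 2100000, with 101 series-level peaks that covered 49.7% of it, against a median of 28 peaks per window on that chromosome. On chromosome III the window from 1500001 to 1600000 held 99 peaks and had 63.8% of its bases in peaks, with 98 peaks in replicate 1 and 88 in replicate 2. Chromosome V had its densest window near the right end, from 19500001 to 19600000 (87 peaks, median 15). Chromosome IV had 83 peaks from 1700001 to 1800000, with 74 in replicate 1 and 47 in replicate 2, and chromosome II had 77 from 1300001 to 1400000. The densest window of X was its left end, from 1 to 100000, with 51 peaks against a median of 11. Only 1 window of the genome, on chromosome V, had no series-level peak.

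The 10 highest-scoring peaks found in both replicates were all on the arms of autosomes, 4 on chromosome III, 3 on chromosome II, 2 on chromosome V and 1 on chromosome IV. The widest of them lay on chromosome III from 1926459 to 1932973 (6515 bp), where replicate 1 had a single peak of 6482 bp and replicate 2 had 2 peaks. A second peak on chromosome III from 1936314 to 1940563 (4250 bp) followed within the same neighbourhood. On chromosome II, the peak from 2920856 to 2926961 (6106 bp) contained the highest-scoring peak of replicate 2 (score 298.64). On chromosome V, the peak from 18539211 to 18543739 (4529 bp) overlapped 1 replicate 1 peak of 4518 bp and 2 replicate 2 peaks of 4409 bp in total. Scores did not separate these peaks from many others, because 100 series-level peaks shared the highest score of 102.28 and the order among them was by width. Gene annotation of WS220 was not used here, so no genes are assigned to these peaks.

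The replicates shared more peaks than rotated lists did, and high-scoring peaks were shared most often. Of the replicate 1 peaks, 10710 of 20533 (52.2%, Wilson 95% interval 51.5 to 52.8%) overlapped a replicate 2 peak, against 11.6% (range 8.86 to 15.9%) after rotation (permutation test by 1000 rotations, two-sided, p = 0.002, the smallest they can give). Of the replicate 2 peaks, 12213 of 16490 (74.1%, interval 73.4 to 74.7%) overlapped a replicate 1 peak, against 15.2% (range 11.3 to 21.2%) after rotation (same permutation test, p = 0.002). With rotation kept within each of the 3 parts of a chromosome, the rotated shares were 13.9% and 18.2% (same permutation test, p = 0.002 in each). With both lists cut to peaks scoring at or above their median, 50.7% of replicate 1 and 71.1% of replicate 2 peaks were shared. In base pairs, 3.97 Mb lay in peaks of both lists, which is 46.7% of the replicate 1 length and 73.0% of the replicate 2 length. In the top score quartile, 86.2% of replicate 1 peaks (interval 85.2 to 87.1%) and 96.8% of replicate 2 peaks (96.2 to 97.3%) were found in the other list. In the bottom quartile the shares were 30.4% (29.2 to 31.7%) and 56.3% (54.8 to 57.8%). No rotated share was computed by quartile. The difference between top and bottom quartile was 55.7 percentage points in replicate 1 and 40.5 in replicate 2. Both values come from the same overlap seen from either list, so they are not independent. When both peaks had to overlap by 50% of their length, the shares were 36.5% and 45.5%, against 2.66% and 3.30% after rotation. Under that rule, 61.1% of replicate 1 and 70.2% of replicate 2 peaks were found in the top quartile, and 20.2% and 24.2% in the bottom quartile.

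**Figure D3:**
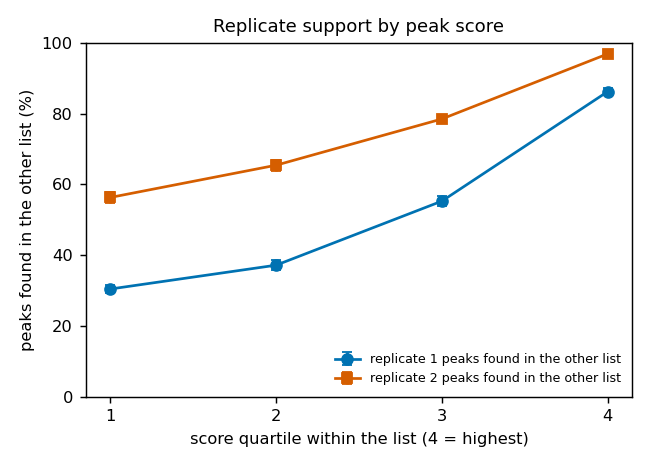
Percent of peaks of each replicate list that overlap a peak of the other replicate by at least 1 bp, by score quartile within the list (4 is the highest), with Wilson 95% intervals as error bars. The share is 30.4% in the lowest and 86.2% in the highest quartile of replicate 1, and 56.3% and 96.8% in those of replicate 2.

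The series-level list contained a larger part of replicate 1 than of replicate 2. It overlapped 98.3% of replicate 1 peaks (interval 98.1 to 98.5%) and 85.6% of replicate 2 peaks (85.1 to 86.2%). Of its 23530 peaks, 10234 (43.5%) were found in both replicates, 9206 (39.1%) in replicate 1 only, 1919 (8.16%) in replicate 2 only and 2171 (9.23%) in neither. Peaks found in both were wider, with a median of 394 bp, than those in replicate 1 only (227 bp), in replicate 2 only (185 bp) or in neither (161 bp). Their median score was 27.5, against 10.6, 6.23 and 4.93 for the other classes in the same order. A wide peak meets the overlap rule of 1 bp more easily, and no expectation matched for width was computed.

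Some peaks appeared in the replicate 2 list alone. On chromosome V between 17115905 and 17131394, replicate 2 had 12 peaks where replicate 1 and the series-level list had none. At the right end of chromosome I, from 15060286 to 15072407, it had 6 peaks with a median score of 25.1 where the other lists had none. These regions were singled out after their values were seen. Further runs of replicate 2 peaks without a peak of the other lists had lower median scores.

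**Figure D4:**
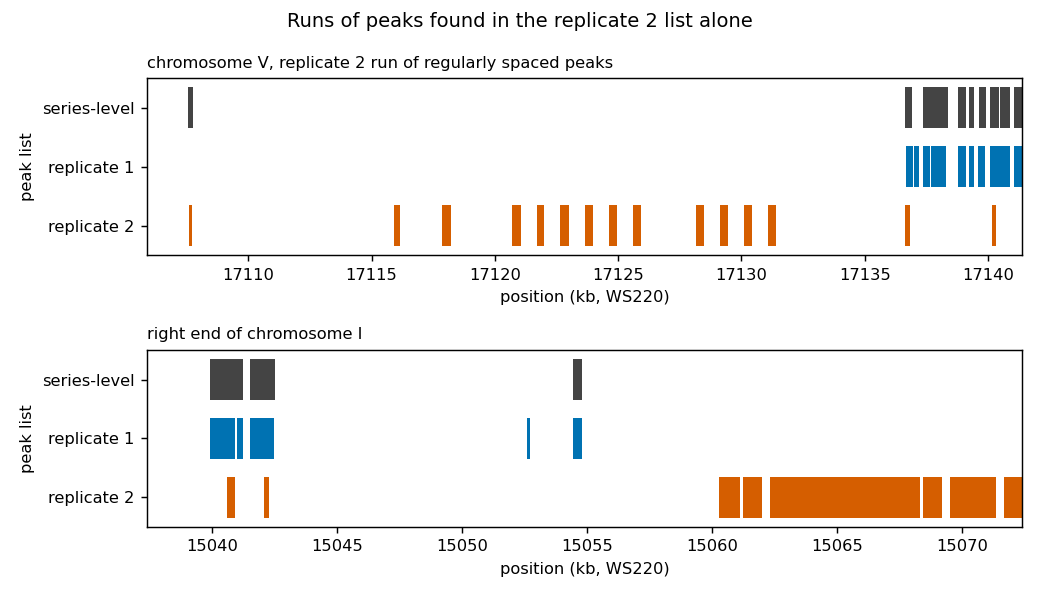
Peaks of the 3 lists, each on a line of its own, drawn to scale against position (kb, WS220) on part of chromosome V and at the right end of chromosome I. Replicate 2 has 12 peaks on chromosome V between 17115905 and 17131394 and 6 peaks on chromosome I beyond 15060286, where the other lists have none.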

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

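Of 32 alternative settings over 7 results, 26 left the direction and the side of the threshold as reported, or moved an untested value by less than the replicate SD. For replicate support by score, that SD came from both directions of the same overlap, so it is a weak yardstick. For the X chromosome, the SD (0.035) came from the 2 replicate lists, which are also 2 of its alternatives, so it is weak there too. The replicate difference in arm ratio, its 3 alternatives (equal list lengths, no chromosome ends or replicate 2 runs on chromosomes V and I, higher scores) and those without series-level peaks found in neither replicate were chosen after seeing the data. Leaving out chromosome ends and these runs kept 16453 of 16490 replicate 2 peaks, too few removed to say anything of stability. The arm ratio was positive under all 9 of its settings, from 0.80 (merged peaks) to 1.92 (peaks found in both replicates), and from 1.19 to 1.83 with a single replicate list. With the autosomes alone it was 1.25 with an exact p = 0.0625, the smallest that 5 chromosomes can give, so the call was lost by construction. The deficit of X kept its sign but moved by more than the replicate SD (log2 ratio -1.40 in base pairs covered, -1.17 for peaks scoring at or above the median, -1.31 for peaks found in both replicates, and -1.16 to -1.11 with a single replicate list), though not without the peaks found in neither replicate (-1.05), and the cause was not tested. Clustering kept its call, but within 5 kb the observed share (92.9%) and the random share (92.2%) were nearly saturated. Replicate sharing exceeded rotation in every setting, from 36.5 to 57.8% of replicate 1 peaks and from 45.5 to 74.1% of replicate 2 peaks. No replicate list can be left out of that comparison. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, have no values analysed here. The 11 alternatives set beforehand for gene annotation and sequence were not run. Peak lists without read counts limit every result to peaks above an unknown threshold, with their positions, widths and scores as deposited.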

Other observations

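All tests in this part were chosen after the results had been seen. Peaks on the arms were slightly wider than those in the centres. The median width, averaged over the 6 chromosomes, was 264 bp on the arms and 241 bp in the centres of the series-level list, 261 and 241 bp in replicate 1, and 234 and 208 bp in replicate 2, and arms were wider on 6 of 6 chromosomes in each list (exact sign-flip permutation test over chromosomes, p = 0.03125 in each). The 2 widest single peaks of the series-level list lay on the X chromosome, which had the lowest peak density. The first ran from 16929461 to 16944229 (14769 bp, right arm) and was called as 2 peaks in replicate 1 and as 20 in replicate 2. The second ran from 7351295 to 7363049 (11755 bp) in the centre of X, with a score of 23.41. It overlapped 2 replicate 1 peaks of 11582 bp in total and 3 replicate 2 peaks of 11202 bp in total. It contains the widest peak of the replicate 2 list (10106 bp). Both were singled out after their widths were seen.

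Higher-scoring peaks lay on the arms more often. In the series-level list the mean log2 arm ratio was 0.77 ± 0.23 (SD over 6 chromosomes) in the bottom score quartile, 1.05 ± 0.22 in the second, 1.29 ± 0.21 in the third, and 1.68 ± 0.38 in the top quartile. The top quartile exceeded the bottom one by 0.91 ± 0.43, on 6 of 6 chromosomes (exact sign-flip permutation test, two-sided, p = 0.03125). The difference was 0.78 ± 0.41 on 6 of 6 chromosomes in replicate 1 (exact p = 0.03125) and 0.66 ± 0.40 on 5 of 6 in replicate 2 (exact p = 0.0625), which did not pass 0.05 and where the bottom quartile (1.69 ± 0.38) lay above the next (1.51 ± 0.33). These tests were run on a pattern already seen and add no independent evidence for it. In replicate 1, peaks that were found in replicate 2 had a log2 arm ratio of 1.93 ± 0.33, and the 9823 that were not had 0.60 ± 0.23. In replicate 2 the values were 1.93 ± 0.31 and, for the 4277 peaks not found in replicate 1, 1.62 ± 0.54. Both lists are denser on the arms, so sorting by overlap itself favours arm peaks. No expectation for this was computed.

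The stronger arm ratio of the replicate 2 list (by 0.64 on the log2 scale) was weighed against technical explanations. With replicate 1 limited to its 16490 highest-scoring peaks, as many as replicate 2 has, the difference was still 0.56 ± 0.25 and positive on 6 of 6 chromosomes, which argues against the shorter list of replicate 2 as the whole cause. Among peaks scoring at or above the median of their list it was 0.65 ± 0.32, again on 6 of 6 chromosomes. The score scale is unknown, so this split may not match peak strength between the lists. It therefore cannot exclude weak peaks in the centres of replicate 1. Shared peaks had a log2 ratio of 1.93 in each list, but they are largely the same places seen from either list. Unshared peaks had 0.60 in replicate 1 (9823 peaks) and 1.62 in replicate 2 (4277 peaks). By the overlap rule, a difference between lists could show mainly among unshared peaks or in their number. These values therefore do not bear on its cause. In the top score quartile the mean log2 ratio was 1.67 ± 0.45 in replicate 1 and 2.35 ± 0.52 in replicate 2. In replicate 1, 49 peaks shared the highest score (82.46), while in replicate 2 a single peak held it (298.64). Peaks of the narrowest width numbered 210 in replicate 1 and 594 in replicate 2. The settings used to call each list are not given. Differences in peak calling, or in read depth, background or enrichment between the libraries, stay open, as does a biological difference between the replicates, which was not tested.

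The replicate 2 list alone held runs of strong peaks in 2 places, the 2 with the highest median scores among runs of at least 5 consecutive peaks without a replicate 1 or series-level peak among them. On chromosome V, 12 peaks lay between 17115905 and 17131394. Of these, 11 scored from 35.23 to 48.98, were 307 to 343 bp wide, and were spaced regularly: 8 of their 10 midpoint distances were 967.5 to 985 bp (median 974 bp), and the others were 2561 and 2846 bp. On chromosome I, 6 peaks filled 10915 bp between 15060286 and 15072407, up to the last position listed for that chromosome. *C. elegans* is known to carry its tandem 5S rRNA genes on chromosome V and its tandem large rRNA genes at the right end of chromosome I, but annotation of WS220 was not used to locate them.

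Technical explanations for these 2 clusters were weighed as follows. For signal too low for the replicate 1 list, the other replicate 2 peaks scoring at least as high as the lowest cluster peak (15.94) were counted. Of these 5244 peaks, 288 were missing from replicate 1 (5.49%, Wilson 95% interval 4.91 to 6.14%), where low signal as a general cause needs most to be. For dilution of replicate 2 signal in the series-level list, 42 of those 288 were missing from it (14.6%, interval 10.97 to 19.1%). Most other peaks of such scores were thus not missing. The clusters were chosen through their absence from both lists, so these shares cannot exclude either explanation at the clusters. A different treatment of repeated sequence when the lists were made (in mapping, in a filter or through the control library) could leave the other lists without any peak there. Their count in the clusters was 0, but the clusters were found through that absence, so different treatment of repeated sequence when the lists were made stays open, as does a real difference between the libraries.

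Replicate 2 also listed a peak at the left end of every chromosome. Its first peak started within 500 bp of position 1 on 6 of 6 chromosomes, against 2 of 6 in replicate 1 and 1 of 6 in the series-level list. The left ends were singled out because of this difference, so no test on them can add to these counts. At the right ends, its last peaks ended 901 to 26952 bp beyond the end of the last series-level peak. The ends of these replicate 2 peaks set the length taken for each chromosome. The scores of the first and last peaks of its 6 chromosomes, 12 in all, had a median of 9.25 and a range of 2.35 to 27.35.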
